A study of Mus musculus with 4 samples.

How the data were processed

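RNA from whole retinas of mice at postnatal day 8 was compared between wild-type littermates (WT) and Opn4-DTA/DTA mice, in which both copies of the melanopsin gene Opn4 carry the diphtheria toxin A chain. Per the labels, each group had 2 libraries on the C57/Bl6 background. The tissue label speaks of dissociated retinal cells, whereas the design text names whole retinal extracts. Directional libraries of polyadenylated RNA were sequenced on an Illumina HiSeq2500, per the labels' protocols. FastQC, STAR, HTSeq and DESeq2 and the genome build mm10 are named in the submitters' processing notes, without versions. The labels do not say whether the 2 libraries of a group came from separate animals, so that p-values measure only the spread between these libraries. Sex-linked genes show that the 2 Opn4-DTA/DTA libraries hold different animals, whereas in WT the spread may be technical only.

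The deposited table has 23336 genes. Per the file headers and the values, it holds for each group the authors' signal, the mean over 2 libraries of gene counts divided by a size factor (normalized counts). It also holds the authors' log2 fold change with its standard error, a test statistic (a score), a p-value and an adjusted p-value. The deposited log2 fold changes are closer to 0 than the log2 ratios of the group means, so they are shrunken. The authors gave an adjusted p-value for 15003 genes, none with a mean under 10 normalized counts. 1 line of the table was empty and is not analysed here. A spreadsheet program had turned 25 gene symbols into dates. A second deposited sheet repeats the rows of 6 genes as cone and rod candidates.

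The deposited values are group means, and the values per library were recovered from them. In each column the low values are sums of whole multiples of 2 fixed steps, 1 step per library. Every mean above 0 was solved for a single pair of whole counts within a relative tolerance of 3e-13, which covered 17757 means in WT and 18327 in Opn4-DTA/DTA. The procedure recovered 20000 of 20000 simulated pairs. Size factors recomputed from the recovered counts by the median of ratios differed from the steps by a relative 2.03e-05 at most. SDs, n = 2 and all tests below rest on these recovered libraries. No recovered library could be tied to a sample label, so the library with the larger size factor in each group is called library a and the other library b. Total counts were 28726275 in WT library a and 22202382 in WT library b. They were 60833968 in Opn4-DTA/DTA library a and 32032295 in Opn4-DTA/DTA library b. A level of 3 counts corresponds to 3.48, 4.59, 1.64 and 3.07 normalized counts in these libraries, in that order. The chi-square of counts over genes, divided by its degrees of freedom, was 30.7 between the WT libraries and 21.9 between the Opn4-DTA/DTA libraries, so neither pair was one library deposited in duplicate.

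Genes with a mean of at least 10 normalized counts were tested, 15003 in all, the same genes for which the authors gave an adjusted p-value. limma 3.58.1 in R 4.3.3 was fitted to log2(normalized count + 1) with a mean-variance trend, without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. This test had been set before the data were examined for a table of normalized values. That the table counts as one was settled once its layout, but not the outcome of the test, was known. Fold changes on this scale understate the change of low genes. In simulated data with 200 changed genes of 15003 and 5 runs, the fit recovered 67.6% of genes changed 1.5-fold, 94.8% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 10.4 false calls per run. The simulation used a dispersion of 0.00751 for every gene and so is optimistic wherever the real spread between libraries was larger. It also differed from the data in its p-values. In it 4.82% of unchanged genes had a p under 0.05, whereas in the data 249 of all 15003 genes did. Ctxn3, 4.66-fold lower in Opn4-DTA/DTA, and Ncoa4, 2.85-fold lower, did not pass (limma adjusted p = 0.780 and 0.208). The simulated shares therefore do not tell how many real changes were missed.

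35 gene lists were fixed before the data were examined. They cover markers of intrinsically photosensitive and all ganglion cells, cones, rods, genes shared by rods and cones, and the photoreceptor synapse. They also cover bipolar, horizontal and amacrine cells, dopamine signalling, Muller glia, reactive glia, astrocytes, microglia, vessels and hypoxia. Tissue that can come along is covered by red blood cell, pigment epithelium, lens, ciliary and corneal, and muscle lists. The others are cell cycle, clock, immediate early, thyroid hormone, nuclear migration, outer limiting membrane, adhesion and guidance, extracellular matrix, interferon, apoptosis, mitochondrial, histone and sex-linked genes, and the neighbours of Opn4. Of 538 listed genes, 521 were in the table, 6 of them under an older symbol. Apart from the sex-linked genes, the 30 lists with at least 5 tested members, a minimum chosen after the data were seen, were compared with all other genes by camera, with a variance trend and a preset correlation of 0.01. The sex-linked list was left out of these tests because it serves to tell the sex of a library. Camera with an estimated correlation and fry were also run. The genes named are Opn4, those past the threshold, the 10 with the lowest p because fewer than 5 passed, list members past the threshold or otherwise up to 2 of the highest mean expression, and the genes of the candidate sheet. Further names are said to be chosen after their values were seen.

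Gene positions are those of the table (mm10). They were compared by symbol with GENCODE M21, which uses the same build. Of 14935 tested genes with a position, 13541 had a symbol there and 13383 overlapped the annotated gene. The other 158 did not overlap it, and for these the annotated position was used. The library kit marks strand, but the sources used here do not say whether counting used it, so values of genes with an antisense or overlapping neighbour are uncertain. The alternatives were another scaling, no filter, other pseudocounts, limma-voom, a fold threshold, each library left out in turn, scaling by library totals, and counts thinned to the shallowest library. Figures were drawn with matplotlib in Python.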

Results

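Gene expression was measured by RNA-seq in whole mouse retina at postnatal day 8, in 2 WT libraries and 2 Opn4-DTA/DTA libraries. Melanopsin, the product of Opn4, is the photopigment of intrinsically photosensitive retinal ganglion cells. Diphtheria toxin A expressed from the Opn4 locus kills the cells that make it. The series title names a role of these ganglion cells in the positioning of cone photoreceptors. The comparison asks which retinal transcripts differ when both Opn4 copies carry the toxin. Loss of melanopsin and loss of the cells cannot be told apart in this design. Total counts ranged from 22202382 to 60833968 per library. All values below are recovered normalized counts, given as mean ± SD with n = 2 per group unless stated otherwise.

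Opn4 was nearly absent from the Opn4-DTA/DTA libraries, which matches their labels. It stood at 337 ± 129 normalized counts in WT and 0.273 ± 0.386 in Opn4-DTA/DTA. The 2 WT libraries had 369 and 161 counts, and the Opn4-DTA/DTA libraries had 1 and 0. The rate was 983 times higher in WT, with an exact 95% interval of 176 to 38882 that covers counting error only. The fitted log2 fold change of -8.03 (SE 0.43, limma adjusted p = 0.00255) depends on the pseudocount. Opn4 lies on chromosome 14 from 34592343 to 34600142 on the minus strand (mm10).

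Besides Opn4, Arr3 rose and Syt15 fell in Opn4-DTA/DTA retinas, and no other gene of 15003 passed the threshold. Arr3 encodes cone arrestin, which shuts off activated cone opsins. It rose 2.89-fold, from 491 ± 70.7 to 1420 ± 25.2 normalized counts, a log2 fold change of 1.54 (SE 0.13, limma adjusted p = 0.0268). Syt15, a member of the synaptotagmin family, was 6.99-fold lower, at 167 ± 4.01 in WT and 23.8 ± 3.34 in Opn4-DTA/DTA. Its log2 fold change was -2.76 (SE 0.24, limma adjusted p = 0.0268). Arr3 is a protein-coding gene on chromosome X from 100605497 to 100618493. Syt15 is a protein-coding gene on chromosome 14 from 34220046 to 34230421, near Opn4. Both libraries of 1 group lay apart from both of the other for all 3 genes. Without the filter on low values Syt15 no longer passed (limma adjusted p = 0.0501). The number of genes past the threshold was 306 without WT library a, 237 without WT library b, 10 without Opn4-DTA/DTA library a and 19 without Opn4-DTA/DTA library b.

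The other 7 of the 10 genes with the lowest p did not pass the threshold. Ncoa4, a receptor for the autophagy of ferritin, also lies on chromosome 14, from 32159892 to 32179363. It stood at 539 ± 114 in WT and 189 ± 18.4 in Opn4-DTA/DTA (limma adjusted p = 0.208). Rdh8, a retinol dehydrogenase of photoreceptor outer segments, stood at 3631 ± 11.8 and 1959 ± 256 (limma adjusted p = 0.208). Values in WT and then Opn4-DTA/DTA were 518 ± 55.0 and 947 ± 46.5 for Hddc3, and 154 ± 68.9 and 33.1 ± 6.70 for Ctxn3. They were 331 ± 43.9 and 149 ± 40.6 for the dopamine receptor gene Drd4, and 43.1 ± 1.84 and 96.4 ± 0.319 for Loxl4, a lysyl oxidase homologue. Hspa8, a constitutive heat shock chaperone, stood at 7124 ± 267 and 10423 ± 657, and its counts are uncertain because near-identical processed copies exist. The adjusted p of these last 5 genes was 0.488 or higher in limma. An unadjusted p under 0.05 was reached by 249 genes, 149 higher and 100 lower, where 750 are expected by chance. The groups lay apart in 23.5% of genes, where chance gives 33.3%, so that for most genes the libraries of the groups overlapped. The WT libraries were the least alike pair (Pearson correlation 0.9891 on the fitted log2 values). Each was closer to Opn4-DTA/DTA library b (0.9928 and 0.9932) than to the other WT library. Such a spread within WT widens the errors of the fit, so these counts do not show that the genotypes barely differ.

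**Figure D1:**
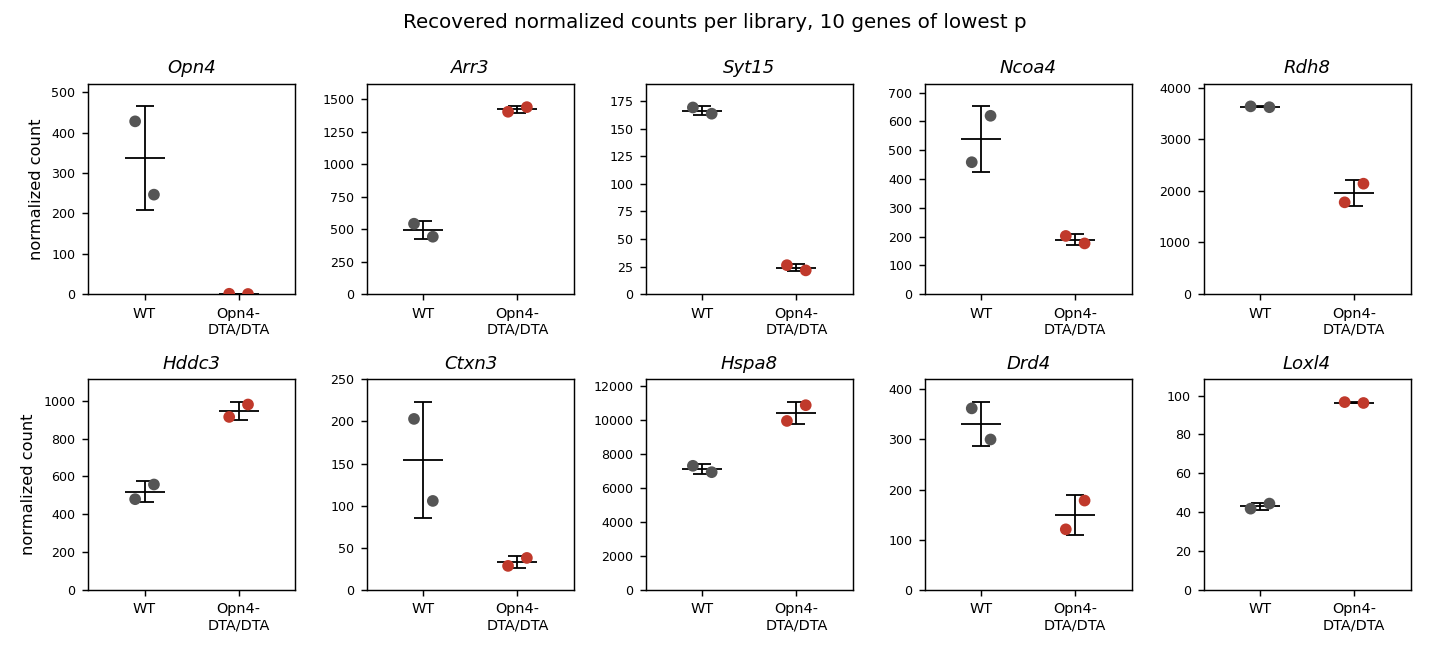
Normalized counts per library (y axis, linear, starting at 0) for the 10 genes with the lowest p, in WT (grey) and Opn4-DTA/DTA (red). Points are the 2 libraries of each group, and bars are mean ± SD. In every panel both libraries of a group lie on the same side of the other group, but only Opn4, Arr3 and Syt15 passed the adjusted threshold.

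**Figure D2:**
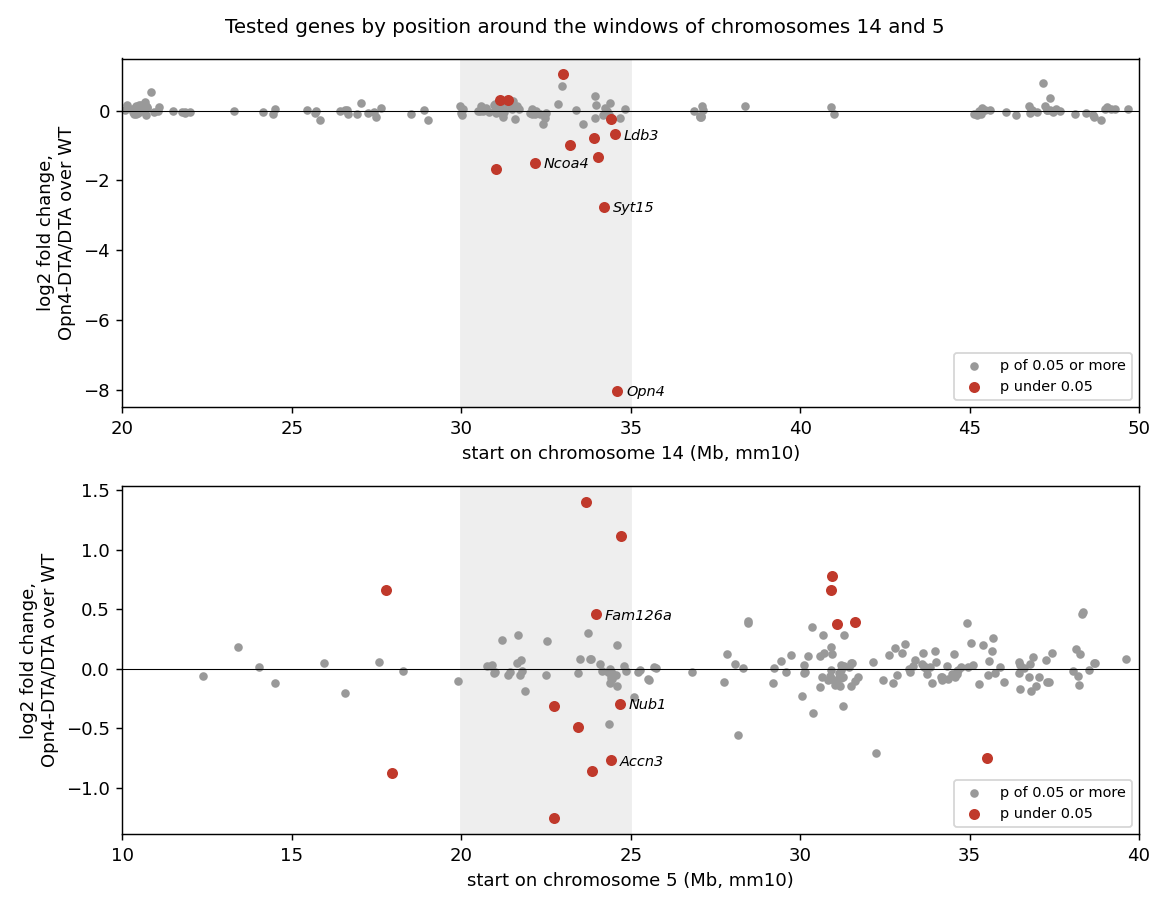
Log2 fold change of tested genes (y axis, Opn4-DTA/DTA over WT) by start position (x axis, Mb, mm10) on chromosomes 14 and 5. Red points have a limma p under 0.05 before adjustment, grey points do not, and shading marks 30 to 35 Mb on chromosome 14, with 12 red of 64 points, and 20 to 25 Mb on chromosome 5, with 9 red of 46.

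The authors' deposited table calls 17 genes at the same threshold, 9 higher and 8 lower in Opn4-DTA/DTA. Higher in the authors' deposited table were Arr3, Hddc3, Hspa8, Lars2, Cdk5rap1, H19, Filip1l, Miat and Fam126a. Lower in the authors' deposited table were Opn4, Rdh8, Syt15, Ncoa4, Pisd-ps1, Accn3, Drd4 and Ctxn3. All 3 limma calls are among the 17 genes of the authors' deposited table, and all 17 had the same sign and groups apart in the recovered libraries. Their unadjusted limma p was 0.00393 or lower. The recovered libraries are the ones behind the deposited values, so that this overlap is not independent evidence for the 17 genes. Of these, Lars2, H19, Miat, Accn3 and Pisd-ps1 are described further because of their values in the table, and were chosen after these were seen. Lars2, a mitochondrial leucyl-tRNA synthetase, was the most abundant of them at 20368 ± 2656 in WT and 28506 ± 827 in Opn4-DTA/DTA. The imprinted noncoding RNA H19 stood at 1897 ± 116 and 2699 ± 320, and the noncoding RNA Miat at 4918 ± 335 and 6674 ± 563. Accn3, a subunit of acid-sensing ion channels, stood at 1473 ± 17.9 and 875 ± 207. Pisd-ps1 is annotated as a transcribed pseudogene, and reads may be divided between it and its parent gene.

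The candidate sheet deposited beside the table holds 5 cone candidates and the rod gene Pde6a, and all 6 had lower means in Opn4-DTA/DTA. Opn1sw, the short-wavelength cone opsin, stood at 10903 ± 473 in WT and 8810 ± 356 in Opn4-DTA/DTA. Tgfb2, a growth factor of the TGF-beta family, stood at 7233 ± 120 and 6195 ± 88.6. Atxn1 stood at 2182 ± 29.4 and 1739 ± 57.9. Pde6a, a subunit of the rod phosphodiesterase, stood at 11689 ± 647 and 9583 ± 958. None of the 6 passed in limma, where Rdh8 came closest. In the authors' deposited table Rdh8 (adjusted p 4.65e-12) and Drd4 (adjusted p 0.00344) passed, and Opn1sw came next with an adjusted p of 0.0563. The sheet repeats rows of the same table, so that it is not independent evidence of their direction.

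By preset correlation, markers of photosensitive ganglion cells lay lower as a set in Opn4-DTA/DTA, with the targeted gene Opn4 among them. Their mean log2 fold change was -0.86 with Opn4 and -0.21 without it. Without Opn4 the median was -0.07 (quartiles -0.16 and 0.02), and 2 of 11 markers changed at least 1.5-fold in either direction. The fall of Opn4 alone does not show a loss of cells, because the allele alters this gene itself. With all libraries, markers of ganglion cells as a whole were not called lower. Of 12 tested photosensitive ganglion cell markers 1 fell, Opn4, and 9 were below 0. The list had a median log2 fold change of -0.10 (camera adjusted p = 0.000254 with a preset correlation, adjusted p = 0.407 with an estimated correlation). Adjusted over the list alone, 2 members passed, Opn4 and Tbx20. The transcription factor gene Tbx20 stood at 259 ± 48.5 in WT and 138 ± 20.2 in Opn4-DTA/DTA. Eomes, also known as Tbr2, stood at 778 ± 277 and 693 ± 45.3. Without Opn4 the list was called at a camera adjusted p of 0.0457 (adjusted p = 0.557 with an estimated correlation). Without WT library a the full list was not called (camera adjusted p = 0.259) and its median was above 0 at 0.03. The median was -0.16 without WT library b and -0.15 without Opn4-DTA/DTA library a. Of 22 pan ganglion cell markers none passed and 19 were above 0, with a median of 0.09 (camera adjusted p = 0.0524). With Opn4 and Arr3 taken out of their lists, the adjustment over lists brought it to 0.0490 in the upper direction (adjusted p = 0.767 with an estimated correlation). The neurofilament gene Nefl stood at 17930 ± 5377 and 18273 ± 107. Without WT library b this list was called in the lower direction (camera adjusted p = 8.65e-08, median -0.18). It was called in the upper direction without WT library a (7.91e-17, median 0.38) and without Opn4-DTA/DTA library a (0.0336).

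Cone markers other than Arr3 mostly had lower values, and the cone list as a whole was not called. Of 18 tested cone markers 1 rose, Arr3, and 12 were below 0. The median log2 fold change was -0.12, the mean was above 0 at 0.01 because of Arr3, and the camera test pointed down (adjusted p = 0.0637, adjusted p = 0.407 with an estimated correlation). Without Arr3 the list was called in the lower direction at a camera adjusted p of 0.00221 (adjusted p = 0.441 with an estimated correlation). Arr3 was taken out after its rise was seen. Leaving out the member that rose most moves the test down by itself, so this call is not separate evidence of a fall. With counts thinned to the shallowest library the full list was called lower (camera adjusted p = 0.0236). It was not called with median-of-ratios rescaling (0.0623), without the filter (0.0669) or with scaling by library totals (0.0519). The median of the full list was -0.12 without WT library a and -0.09 without WT library b. It was -0.09 without Opn4-DTA/DTA library a and -0.13 without Opn4-DTA/DTA library b. Gnb3, a transducin subunit of cones and ON bipolar cells, stood at 21445 ± 2026 in WT and 18210 ± 243 in Opn4-DTA/DTA. Adjusted over the list alone, Arr3 remained the single cone marker that passed.

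Rod, shared photoreceptor, photoreceptor synapse and bipolar lists lay lower as sets in Opn4-DTA/DTA by preset correlation, with no single member past the threshold. Of 18 rod markers 17 were below 0 (median -0.20, camera adjusted p = 3.60e-10, adjusted p = 0.407 with an estimated correlation). Of 20 genes shared by rods and cones 18 were below 0 (median -0.16, camera adjusted p = 1.93e-09, adjusted p = 0.407 with an estimated correlation), among them the phosducin gene Pdc at 92214 ± 12034 in WT and 82145 ± 686 in Opn4-DTA/DTA. Of 16 ribbon synapse genes 15 were below 0 (median -0.16, camera adjusted p = 8.71e-08, adjusted p = 0.407 with an estimated correlation). Of 19 bipolar markers all 19 were below 0 (median -0.21, camera adjusted p = 3.60e-10, adjusted p = 0.407 with an estimated correlation). The rod call was lost without WT library a (camera adjusted p = 0.0784) and the bipolar call without WT library b (camera adjusted p = 0.169). The rod median was then -0.06, and -0.31 without WT library b. The bipolar median was -0.06 without WT library b, -0.11 without Opn4-DTA/DTA library a and -0.32 without WT library a.

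Cell cycle and progenitor genes lay higher as a set in Opn4-DTA/DTA, with 15 of 18 above 0 and a median log2 fold change of 0.25. The camera adjusted p was 3.60e-10, and adjusted p = 0.407 with an estimated correlation. Without WT library b the median was 0.40. No member passed over all genes, and adjusted over the list alone 1 passed, Ccnb1. This cyclin gene of mitosis stood at 49.4 ± 0.654 in WT and 112 ± 18.9 in Opn4-DTA/DTA. Ccnd1, the cyclin of G1 phase, stood at 5225 ± 798 and 6311 ± 41.9. Pcna, the sliding clamp of DNA replication, went the other way at 1467 ± 122 and 1348 ± 35.8.

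Other inner retinal and glial lists were not called. The median log2 fold change was 0.01 for 10 horizontal cell markers (camera adjusted p = 0.674, with mean and test pointing down), 0.07 for 20 amacrine markers (0.0838) and -0.03 for 16 Muller glia markers (0.270). It was -0.05 for 12 genes of reactive glia (camera adjusted p = 0.218) and 0.04 for 7 astrocyte markers (0.349). Examples are Tfap2b of amacrine cells, at 14088 ± 380 in WT and 15067 ± 1211 in Opn4-DTA/DTA, and Dkk3 of Muller glia, at 16673 ± 398 and 17400 ± 683. Of 10 dopamine genes 7 were above 0 (median 0.20, camera adjusted p = 0.561), and adjusted over the list alone only Drd4 passed. The dopamine median was 0.40 without WT library a and -0.01 without WT library b, and that of Muller glia was 0.03 without WT library b and -0.07 without Opn4-DTA/DTA library b. Without WT library b the lists of reactive glia (camera adjusted p = 0.0190, median -0.35) and astrocytes (0.0448, median -0.19) were called in the lower direction. Without WT library a that of astrocytes was called in the upper direction (0.000447, median 0.34), and the median of reactive glia was 0.05. It was -0.14 without Opn4-DTA/DTA library b.

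Microglia, vessel, and ciliary and corneal lists lay higher as sets, the pigment epithelium list lower, and each of the 4 turned direction when 1 library was left out. Of 17 microglia genes 13 were above 0 (median 0.11, camera adjusted p = 0.0106, adjusted p = 0.678 with an estimated correlation). Of 15 vessel genes 13 were above 0 (median 0.14, camera adjusted p = 0.00155, adjusted p = 0.568 with an estimated correlation). Of 10 ciliary and corneal genes 8 were above 0 (median 0.09, camera adjusted p = 0.0377, adjusted p = 0.678 with an estimated correlation). These 3 turned without WT library b, to a camera adjusted p of 0.258, 0.278 and 0.429 and a median of -0.15, -0.10 and -0.02. Without WT library a their medians were 0.45, 0.40 and 0.36, and that of microglia was 0.26 without Opn4-DTA/DTA library a and 0.03 without library b. Without Opn4-DTA/DTA library b the microglia (0.376) and ciliary and corneal (0.115) calls were lost, and without Opn4-DTA/DTA library a the ciliary and corneal call (0.173). With all libraries the ciliary and corneal call was also lost without the filter (0.487) and with scaling by library totals (0.0693), and the microglia call in camera without a variance trend (0.0548). Of 14 pigment cell genes 12 were below 0 (median -0.22, camera adjusted p = 0.0121, adjusted p = 0.678 with an estimated correlation), and without WT library a the list was called in the upper direction (camera adjusted p = 0.00157). Without Opn4-DTA/DTA library b it was not called (0.218). Its median was 0.23 without WT library a, -0.73 without WT library b, -0.36 without Opn4-DTA/DTA library a and -0.10 without Opn4-DTA/DTA library b. Ttr, which the pigment epithelium expresses strongly, had 3365 normalized counts in WT library a and 1307 in WT library b, against 1843 and 1352 in the Opn4-DTA/DTA libraries.

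Lens genes lay higher as a set, with 5 of 7 above 0 and a median of 0.51 (camera adjusted p = 0.00530, adjusted p = 0.407 with an estimated correlation). The call was lost without Opn4-DTA/DTA library a (camera adjusted p = 0.648, median 0.33) and without WT library b (0.169, median 0.28), and the median was 0.78 without Opn4-DTA/DTA library b. Without the filter the median was 1.09 (camera adjusted p = 0.000131). The alpha crystallin gene Cryaa, named after its values were seen, had 156 normalized counts in Opn4-DTA/DTA library a against 3.07 in library b, and 6.96 and 0 in the WT libraries. The 2 tested red blood cell genes, under the minimum for the set tests, both passed when adjusted over the list alone. With lists of at least 1 tested member this list was called higher (camera adjusted p = 0.000117, adjusted p = 0.416 with an estimated correlation). The beta globin gene Beta-s stood at 968 ± 153 in WT and 1287 ± 18.2 in Opn4-DTA/DTA, uncertain for its near-identical copies, and Alas2 stood at 77.9 ± 12.8 and 119 ± 7.97. The 4 tested muscle genes had a median of -0.02.

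Among the remaining lists, interferon genes and adhesion and guidance genes lay lower as sets. Of 15 interferon genes 14 were below 0 (median -0.15, camera adjusted p = 0.0296, adjusted p = 0.407 with an estimated correlation). The interferon call was lost without WT library a (camera adjusted p = 0.0615), WT library b (0.549, median -0.09) or Opn4-DTA/DTA library a (0.324, median -0.09). Of 26 adhesion and guidance genes 19 were below 0 (median -0.06, camera adjusted p = 0.0241, adjusted p = 0.568 with an estimated correlation), and the call was lost without WT library b (camera adjusted p = 0.966, median -0.04) and turned direction without Opn4-DTA/DTA library b (0.968, median 0.01). The adhesion and guidance median was -0.16 without WT library a and -0.09 without Opn4-DTA/DTA library a. Not called were 13 hypoxia genes (median 0.04, camera adjusted p = 0.185), 21 clock genes (0.01, 0.674), 17 immediate early genes (-0.04, 0.506) and 13 thyroid hormone genes (-0.07, 0.0568). The same held for 19 genes of nuclear migration (0.01, 0.990), 17 of the outer limiting membrane (-0.04, 0.0551), 17 of the extracellular matrix (-0.02, 0.872) and 14 of apoptosis (-0.01, 0.674). Dctn1, a dynactin subunit of the nuclear migration list, stood at 22656 ± 106 in WT and 20645 ± 271 in Opn4-DTA/DTA. The camera test of the clock list pointed down although its median was above 0. Adjusted over the list alone, Col1a2 of the extracellular matrix list passed, at 503 ± 45.6 and 324 ± 20.1. Of 8 neighbours of Opn4, 5 were below 0 (median -0.07, camera adjusted p = 0.0613). The immediate early median was above 0 at 0.04 without Opn4-DTA/DTA library a, and the thyroid median was -0.03 without WT library a or Opn4-DTA/DTA library b. With 1 library left out some of these lists were called. Neighbours of Opn4 were called lower without WT library b (0.0322, median -0.11) or Opn4-DTA/DTA library a (0.0215), but without WT library a their median was above 0 at 0.03 (0.727). The outer limiting membrane list was called lower without WT library a (0.0102, median -0.09), and the extracellular matrix list lower without Opn4-DTA/DTA library a (0.0336, median -0.11), whereas without WT library a the latter had a median of 0.20. Hypoxia genes were called lower without WT library a (0.0320, median -0.15), and higher without WT library b (1.87e-05, median 0.16) or Opn4-DTA/DTA library a (0.000267, median 0.10). The 4 tested histone genes had a median of -0.14, and no mitochondrially encoded gene was in the tested set. In all, 13 of 30 lists were called with a preset correlation, 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and 0 with fry. The estimated correlation was -0.03 for shared photoreceptor, -0.01 for interferon and 0.02 for ribbon synapse genes, close to the preset 0.01. In the other called lists it ran from 0.12 (cell cycle) to 0.87 (pigment cells). Calls with an estimate near the preset were lost too, so a higher correlation alone does not account for the loss. The adjusted value of 0.407 given for many lists is a tie made by the adjustment, and does not rank them. In lists for which no gene is named as such, no member passed when adjusted over the list alone.

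**Figure D3:**
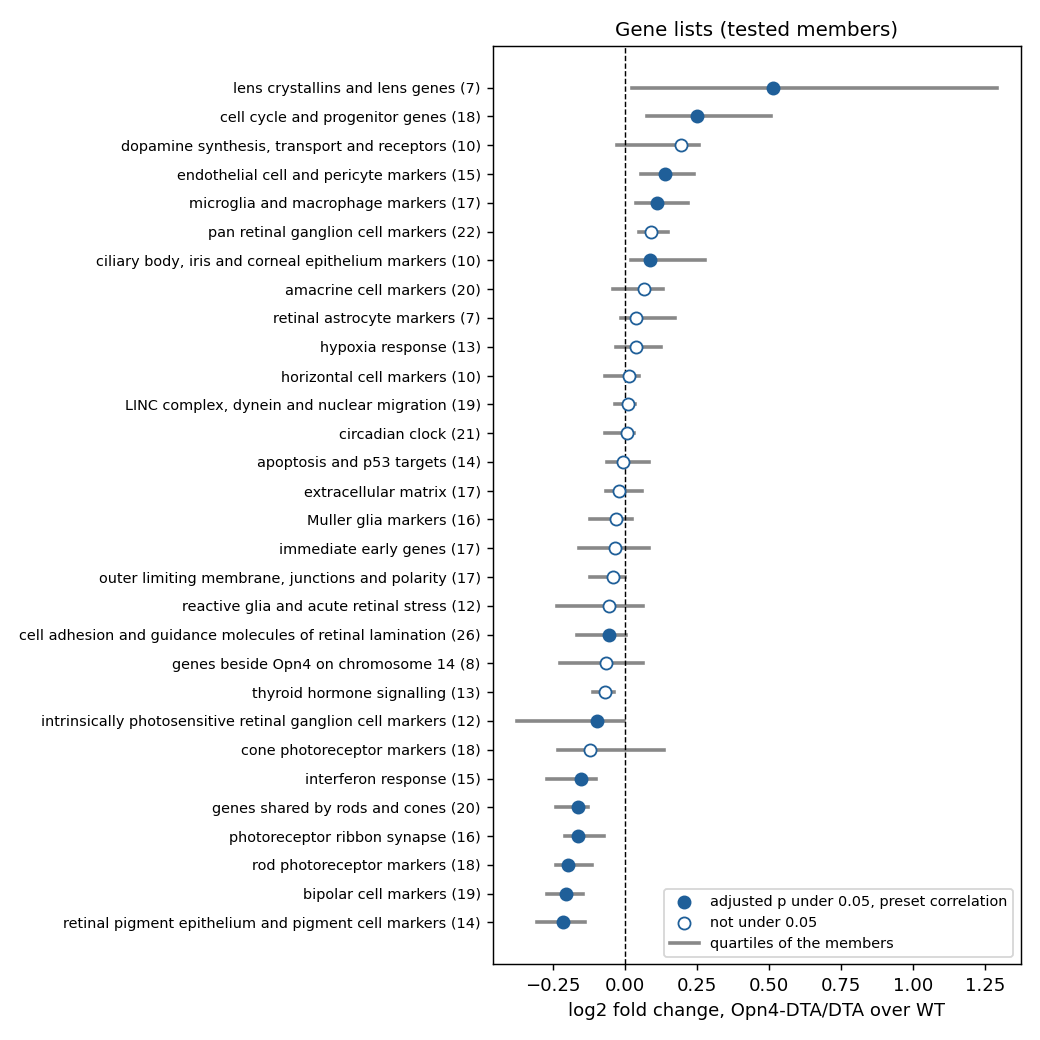
Median log2 fold change (x axis, Opn4-DTA/DTA over WT) of the tested members of 30 gene lists (y axis, number of tested members in parentheses), with lines from the lower to the upper quartile. Filled points mark the 13 lists with an adjusted p under 0.05 at a preset correlation, none of which held with an estimated correlation.

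The sex-linked genes differed between libraries of 1 group. Opn4-DTA/DTA library a had 4178 normalized counts of the Y-linked gene Ddx3y and 47.0 of Xist, which is expressed from the inactive X chromosome. The other 3 libraries had 0 of Ddx3y and between 61811 and 96533 of Xist. Arr3, which is X-linked, stood at 1402 in this male library and at 1438 in the female Opn4-DTA/DTA library.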

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

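Scaling by library totals, thinned counts, the lists without their leading genes, other camera settings, other windows and the use of the authors' adjusted p were chosen after the data were seen. Count tests on the recovered counts were planned and not run. No paired analysis was possible because the labels give no number shared between the groups. The call of Opn4 held in every alternative, and those of Opn4 and Arr3 in all limma alternatives; Syt15 was lost only without the filter, where 2 genes passed. The other scalings, pseudocounts, limma-voom, the fold threshold and thinning gave 3 genes each, and the authors' deposited adjusted p gave 17 genes. Leaving out 1 library gave 10 to 306 genes. The lone library is then assumed to vary like the other group; without WT library a 306 passed, without WT library b 237, without Opn4-DTA/DTA library a 10 and without Opn4-DTA/DTA library b 19, the last including sex-linked genes. The cause of the differences was not tested, the smaller number of samples included. Depth limits genes near 3 counts, and library totals ran from 22202382 to 60833968.

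The 13 list calls fell to 0 with an estimated correlation and 0 with fry, and lay between 9 and 14 with 1 library left out and between 12 and 19 in the other alternatives. Thinning called 6 more, lower for cone (0.0236), thyroid (0.0283), outer limiting membrane (0.0236) and Opn4 neighbour lists (0.0258) and higher for ganglion (0.0236) and amacrine cells (0.0350). Directions turned for the lists below. The range is the camera adjusted p over the 4 left-out libraries, and the cause was not tested. Nuclear migration turned without the filter (0.877), with thinned counts (0.955), with fry (0.974) and without WT library a or Opn4-DTA/DTA library a (range 0.369 to 0.606). Extracellular matrix turned with thinned counts (0.955) and without WT library a or Opn4-DTA/DTA library b (range 0.0336 to 0.218). Without WT library a, reactive glia (range 0.0190 to 0.789), hypoxia (1.87e-05 to 0.697) and pigment cells (1.94e-16 to 0.218) turned. Without WT library b, ganglion cells (7.91e-17 to 0.0908), horizontal cells (0.587 to 0.966), dopamine (0.120 to 0.750), astrocytes (0.000447 to 0.461), microglia (1.65e-10 to 0.376), vessels (5.47e-09 to 0.278) and ciliary and corneal genes (0.000608 to 0.429) turned. Without Opn4-DTA/DTA library b, dopamine, hypoxia, clock (0.295 to 0.985), adhesion and guidance (0.000107 to 0.968) and apoptosis (0.727 to 0.984) turned.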

Other observations

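The tests on chromosome windows, on Arr3 and on the share of photoreceptors were chosen after the results they concern were seen. Those on further cell cycle genes and on left-out libraries were set before.

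Genes on chromosome 14 around Opn4 held an excess of low p-values. In the 5 Mb window from 30 to 35 Mb, 12 of 64 tested genes had a limma p under 0.05, where 1.05 are expected (exact hypergeometric adjusted p = 2.38e-07 over 532 windows). Besides Opn4, Syt15 and Ncoa4 these include Gdf10, a growth factor of the BMP family, at 267 ± 48.9 in WT and 152 ± 3.62 in Opn4-DTA/DTA (SD, n = 2), and Bmpr1a, a BMP receptor, at 4670 ± 412 and 3952 ± 57.5. These further genes were chosen after their values were seen and did not pass over all genes. Of the 12 low-p genes 9 were lower and 3 higher in Opn4-DTA/DTA. Some had low counts, such as Lrrc18 at 11.7 ± 5.08 in WT and 24.0 ± 0.765 in Opn4-DTA/DTA. A second window, on chromosome 5 from 20 to 25 Mb, had 9 of 46 genes, 6 lower and 3 higher, where 0.755 are expected (exact hypergeometric adjusted p = 1.28e-05). Fam126a, Accn3 and Nub1 lie in it. With the positions as deposited, where Nub1 and the Opn4 neighbour Ldb3 carry the place of other genes, the adjusted p of the 2 windows was 3.40e-06 and 0.000159. With the p of the authors' deposited table it was 6.59e-05 and 0.000149, and a window on chromosome 4 from 60 to 65 Mb also passed (0.0132).

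For these crowded windows, an effect of the inserted cassette on genes within 0.5 Mb only is argued against. Low-p genes were also more frequent at 0.5 to 5 Mb from Opn4 than over 20 Mb away or on other chromosomes (one-sided Fisher's exact p = 7.70e-06). They are among the genes that marked the window on chromosome 14, so that this p restates its excess. A linked segment of another strain, carried with the targeted allele, may account for the window on chromosome 14. The share of low-p genes was 15.1% within 5 Mb of Opn4 and 1.57% on other chromosomes, and over 20 Mb away on chromosome 14 it was 1.65% (one-sided Fisher's exact p = 0.522 against other chromosomes). For chromosome 5, reads shared between overlapping genes are argued against, since 7 of the 36 genes that overlap no other tested gene had a low p (exact hypergeometric p = 1.63e-06). This p is not adjusted for the choice of the window on chromosome 5 by its excess. Whether the 9 genes there lie in a segment of another strain stays open because the table holds no sequence, and loss of the ganglion cells as the cause of either window was not tested.

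Arr3 stood apart from other cone markers. The sex of the animals is argued against, as the female Opn4-DTA/DTA library had 2.66 times the Arr3 level of the highest WT library, all 3 being female. More cones in the sample are argued against, as the other 17 cone markers had a median log2 fold change of -0.12 (quartiles -0.23 and 0.13) against 1.54 for Arr3. A crowding of low-p genes like that around Opn4 was not seen around Arr3. Within 5 Mb of Arr3, 1 of 57 genes had a low p (one-sided Fisher's exact p = 0.603 against other chromosomes). The exact 95% upper bound of 9.39% lay below the 15.1% near Opn4, a share that is itself uncertain. A short strain segment around Arr3 could not be excluded. Only 8 genes were tested within 0.5 Mb, 0 of them with a low p, and the upper bound there was 36.9%. A response of cones to the loss of photosensitive ganglion cells or of melanopsin stays open as a hypothesis. These data may raise it but did not test it, and a variant in Arr3 itself was not tested.

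Photoreceptor and bipolar lists lay lower and the cell cycle list higher in Opn4-DTA/DTA by preset correlation, with adjusted p = 0.407 with an estimated correlation for each. For a direction set by 1 library, 0 of 16 combinations of 4 lists and 4 left-out libraries turned. This argues against it for the shared photoreceptor and cell cycle lists, whose library means lay apart by group. For rods and bipolar cells it cannot decide, because the size leans on 1 WT library. The median was -0.06 for rods without WT library a and for bipolar cells without WT library b, against -0.20 and -0.21 with all. The mean log2 value of the rod list was 14.51 and 14.30 in WT libraries a and b, and 14.16 and 14.27 in Opn4-DTA/DTA libraries a and b. That of the bipolar list was 10.80 in WT library a and 10.86 in Opn4-DTA/DTA library b. A lower share of photoreceptors could not be excluded. It predicts higher values for all other retinal types. Mean log2 fold changes were 0.08 for the ganglion and 0.05 for the amacrine list. They were -0.01 for the horizontal, -0.05 for the Muller glia and -0.22 for the bipolar list. These lower means go against the prediction, but the bipolar libraries did not separate by group, so that the question is not decided. More cells in the cell cycle, possibly from a younger developmental state, also stays open: 24 of 25 further G2 and M phase genes were above 0 (median 0.28), and so were 18 of 25 further S phase genes, with a lower median of 0.0577. The S phase median lay below the other by 0.22, more than either interquartile range (0.21 and 0.19), and a gap beyond these ranges was set beforehand as speaking against it, but that bound was wrong, because both medians above 0, set as speaking for it, held for the same values, and the verdict was changed to open after they were seen.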
